A study of Mus musculus with 12 samples.

How the data were processed

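Total RNA of 4 mouse acute myeloid leukaemia (AML) cell lines was measured on 12 one-colour expression arrays with probe sets of the Affymetrix kind, 3 arrays per line. B117P and B140P are parental lines described as sensitive to cytarabine (Ara-C), and B117H and B140H are the highly resistant lines derived from them. Per the labels' protocols, RNA was extracted with RNeasy Midi kits and amplified and biotin-labelled with a MessageAmp kit. The same protocol text, exposure to rising Ara-C concentrations and passage in medium without the drug, stands with all 12 samples, so it does not separate parental from resistant cells. Each line's arrays carry the letters A, B and C. Nothing in the labels says that they came from separate cultures, so the p-values measure only the spread between these samples.

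The deposited values are RMA-summarised probe-set intensities, 1 column per array, as the submitters' processing notes name RMA. The RMA version and settings are not given in the sources used here. That the deposited intensity values are on a linear scale was read from the values: they ran from 7.65 to 36675, and the array medians lay between 118 and 132. They were put on the log2 scale as log2(value + 1), with a pseudocount of 1, so folds are on that scale. No detection calls came with the values, and RMA compresses differences among low values, so changes of dim probe sets are understated.

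Of the 45101 probe sets, 64 array controls were left out and 45037 were tested. The platform annotation paired 34945 of the tested probe sets with 1 gene symbol, 932 with several and 9160 with none, and no gene was named from a probe set with several. A gene was represented by its one-symbol probe set with the highest mean over all 12 arrays, which gave 18193 genes, 9010 of them with several probe sets. The reference gene table (assembly GRCm38.p6) matched 18032 of these genes and changed 0 symbols. It was used only for chromosomes and gene positions, on which the windows and distances below rest. No genome build is given in the sources used here.

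The model was limma 3.58.1 in R 4.3.3, with lmFit, contrasts.fit and eBayes on all 12 arrays and 1 coefficient per line, two-sided. Adjusted p-values are Benjamini-Hochberg values over the 45037 probe sets, and a gene was called with an adjusted p under 0.05. The contrasts were each resistant line minus its parental line, the average of these 2 changes, the difference between them and the 2 parental lines. The prior had 4.65 degrees of freedom beside 8 residual degrees. The median residual SD was 0.154 log2 units, and the median gene had a 95% interval of a factor of 1.20 to either side of its fold change. The number of arrays limits this precision. Gene lists were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated from the data, over the 30 lists. These lists held 967 measured genes of 1072 symbols and covered drug handling, nucleotide metabolism, genome maintenance, cell death, cell cycle, stress, metabolism and the markers of the cell types that the cultures could hold. The 21 chromosomes were tested in the same way.

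The groups, the contrasts, the lists, the rule for naming genes and most alternative settings were fixed before the data were examined. By that rule the text may name, per pair, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose 3 resistant arrays all lay on one side of the 3 parental arrays. It may also name the 10 genes that rose and the 10 that fell in both pairs, the 5 with the largest difference between pairs, Dck and the members of the lists of Ara-C uptake and activation and of Ara-C inactivation. From any other list it may name the 4 called members with the largest change per comparison. Predicted genes and Riken names were left out. The tests over windows of neighbouring genes, the comparison of C with A arrays and 5 alternatives were chosen after the data had been seen.

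The replicate letters were checked by the correlation, across probe sets, of the arrays' deviations from their line's mean. Between B140P and B140H it was 0.587 for A, 0.360 for B and 0.560 for C. Between B117H and B140P it was 0.567, 0.367 and 0.493, and between B117H and B140H 0.455, 0.349 and 0.532. Between B117P and B140P it was 0.499, 0.131 and 0.414. So the letters pair the arrays of B117H, B140P and B140H, across lineages too, while in B117P only A and C match. The main fit holds no term for the letter. A fit with the letter as a block was run as an alternative. The other settings tried were fits on the pair's own arrays, quantile normalization applied again, centring on array medians, brighter probe sets only, an intensity trend with robust priors, array weights, the mean of a gene's probe sets, an adjusted p under 0.01, a test against a fold of 1.5 and leaving out each array in turn. Those added later were log2 without a pseudocount, leaving out probe sets with names ending in _s_at or _x_at, leaving out all A or all C arrays, and list tests without genes of moved chromosome segments.

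The steps were tested on simulated data made from the B117H and B117P arrays, with 200 of 18193 genes changed. Where all probe sets of a gene were changed, 17 of 67 genes changed by 0.5 log2 units were called, 66 of 67 changed by 1 and 66 of 66 changed by 2, with 8 false calls among 157. Where only the brightest probe set was changed, 16 of 67, 61 of 67 and 59 of 66 were called, and another probe set then stood for 1, 4 and 7 of these genes. In the simulated B140 pair, where no gene was changed, limma called 0 genes, and 842 had an unadjusted p under 0.05. The cholesterol synthesis list moved by 0.3 log2 units was called upward with 0 other lists, and 0 of 30 lists were called in the simulated B140 pair, where none was moved. The simulated noise was independent between probe sets and held no effect of the letters. It could therefore not show how camera behaves where genes of a list vary together.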

Results

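Transcript levels were measured in 4 mouse leukaemia cell lines that go back to BXH-2 mice, an inbred strain in which a replicating retrovirus causes myeloid leukaemia. B117P and B140P are parental lines that are sensitive to Ara-C, a cytidine analogue that stops DNA synthesis once the cell has phosphorylated it. B117H was derived from B117P and B140H from B140P, and both tolerate high doses of the drug. Each line had 3 arrays, named A, B and C. Array medians lay between 118 and 132 intensity units on the linear RMA scale. Across probe sets, arrays of the same line correlated at 0.988 to 0.997, and arrays of different lineages at 0.967 or less. Array B of B140H stood apart, with a lower quartile of 58.6 and a median of 132 intensity units. All changes below are log2 values of the resistant line minus its own parental line, called with limma at an adjusted p under 0.05.

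Dck fell in both resistant lines. It encodes deoxycytidine kinase, which adds the first phosphate to Ara-C and without which the drug stays inactive. By its brightest and next brightest probe sets the fall was far larger in B117H than in B140H. Their signal came close to the lowest intensities on the arrays in B117H, and part of it remained in B140H. The third probe set fell in B140H but not in B117H. Dck lies on chromosome 5 of the mouse.

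The brightest Dck probe set measured 2794 ± 453 intensity units (SD, n = 3) in B117P and 10.2 ± 0.922 in B117H. This was a log2 change of -7.96 (adjusted p = 7.73e-13), whose size is not exact, since the lowest intensity on any array was 7.65 and no measure of background came with the values. The same probe set measured 2465 ± 120.3 intensity units (SD, n = 3) in B140P and 298 ± 15.3 in B140H, a log2 change of -3.04 (adjusted p = 1.92e-08), or 8.24-fold. The difference between the lines was 4.92 (adjusted p = 2.56e-08), no more exact than the change in B117H. The next brightest Dck probe set changed by -6.43 in B117H (adjusted p = 1.52e-10) and by -2.90 in B140H (adjusted p = 4.14e-07). The third probe set of the gene behaved otherwise. It changed by -1.41 in B140H (adjusted p = 0.000365) but by -0.12 in B117H (adjusted p = 0.913), and the difference between the lines was -1.28 (adjusted p = 0.00551). Values as low as those of Dck in B117H are compressed by RMA, those of the next brightest probe set (13.8 intensity units) included.

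**Figure D1:**
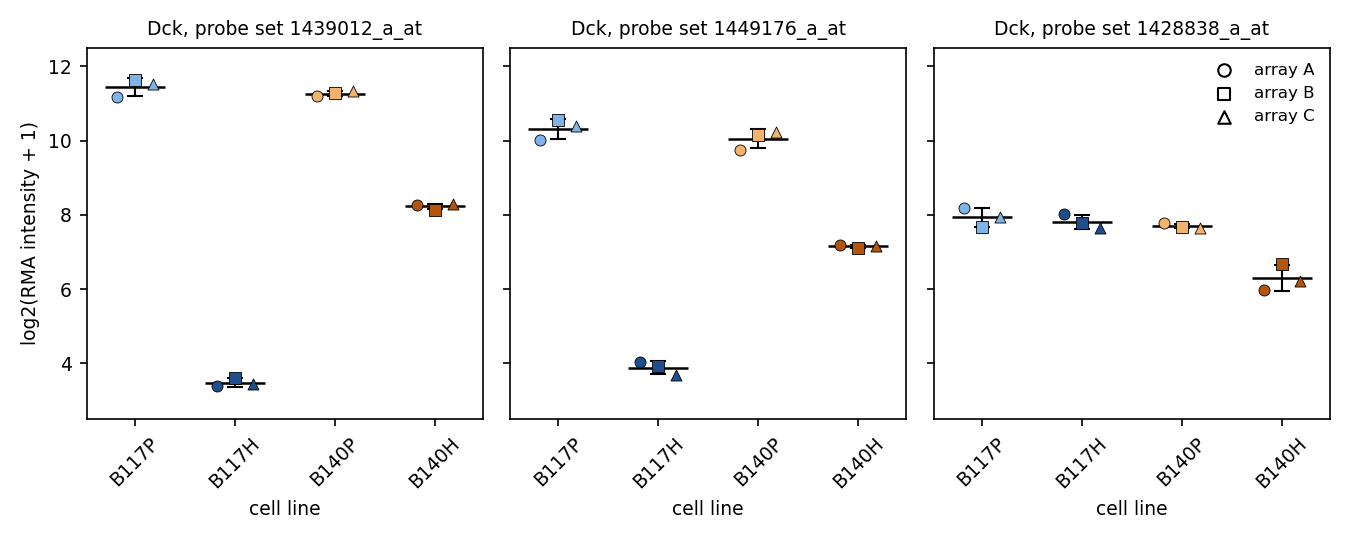
Level of Dck as log2(RMA intensity + 1) in the 4 cell lines for its 3 probe sets, 1 symbol per array, with the mean and SD of the 3 arrays. For the brightest probe set (left) the means are 11.44 in B117P, 3.48 in B117H, 11.27 in B140P and 8.22 in B140H.

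Few other genes of Ara-C handling were called. Dguok, the mitochondrial kinase that phosphorylates deoxyguanosine, rose in both resistant lines, and Nt5c3b, a nucleotidase, rose in B117H. Slc29a1, the nucleoside transporter that lets Ara-C into cells, and Cmpk1, the kinase for the next phosphate, passed no test in either line. The same was true of Cda, the deaminase that inactivates Ara-C, and of Samhd1, which hydrolyses its triphosphate.

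Dguok changed by 0.49 in B117H (adjusted p = 0.00589) and by 0.43 in B140H (adjusted p = 0.0197). Its B117H call ended without all C arrays (adjusted p = 0.188). Its B140H call ended without all A (adjusted p = 0.0657) or all C arrays (0.303), without B140P B (0.107), B140P C (0.0848), B140H A (0.064) or B140H C (0.0582), with arrays centred on their medians (0.059) and with only the pair's arrays in the fit (0.104). Nt5c3b changed by 0.70 in B117H (adjusted p = 0.0161), a call that ended without B117P B (adjusted p = 0.0615), B117P C (0.0826), B117H B (0.0783), B117H C (0.0512) or all C arrays (0.242). It changed by 0.10 in B140H (adjusted p = 0.842). Slc29a1 changed by 0.18 and 0.38 in B117H and B140H (adjusted p = 0.86 and 0.41), and Cmpk1 by -0.04 and 0.15 (0.963 and 0.551). Samhd1 changed by 0.22 and 0.21 (0.175 and 0.238). Cda stood at log2 levels of 6.25, 6.29, 6.29 and 6.47 in B117P, B117H, B140P and B140H, below the median of all probe sets, 6.95. Dctd, a deaminase of deoxycytidylate, fell in the average of both pairs by 0.29 (adjusted p = 0.0376). Its change of -0.34 in B117H was not called (adjusted p = 0.0852), except with brighter probe sets only (0.0447) and with the mean of a gene's probe sets (0.0409).

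Of the 13 measured genes of Ara-C uptake and activation, 1 rose and 1 fell in each resistant line, the pair being Dguok and Dck. Adjusted over the list alone, 1 rose and 3 fell in B117H, and 1 rose and 1 fell in B140H. Camera gave an adjusted p of 0.149 in B117H and 0.536 in B140H. Of the 13 measured genes of Ara-C inactivation, 1 rose and 0 fell in B117H, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.951). In B140H limma called 0 of them, also 0 adjusted over the list alone, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.613).

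B117H was compared with B117P to find what else changed as this line became resistant. Glul, which encodes glutamine synthetase, and Depdc1a, a gene of dividing cells, went from near the floor to high levels, and Sgpp1, a sphingosine phosphate phosphatase, and Nrg4, a growth factor, also rose. The pre-B-cell gene Vpreb1 and the integrin gene Itgax rose as well. Behind Dck, the largest falls were those of Uty, a demethylase gene of the Y chromosome, Hpgd, which degrades prostaglandins, the membrane protein gene Igsf6 and Hpse, which encodes heparanase. Nsd1, a histone methyltransferase gene, and the myeloid genes Ms4a3 and Ms4a6d fell too.

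Glul rose from a log2 level of 4.11 ± 0.25 (SD, n = 3) to 9.46 ± 0.12, a change of 5.35 (adjusted p = 1.23e-09) whose size is not exact either, and stood at 9.70 in B140P. Depdc1a rose by 4.89, Sgpp1 by 3.91 and Nrg4 by 3.34. Itgax, the amino acid transporter gene Slc36a4 and Acss2, which makes acetyl-CoA from acetate, rose by 2.96, 2.95 and 2.87. Vpreb1 rose by 2.78, Lpcat2, an acyltransferase of phospholipids, by 2.68, and Crem, a transcription factor of the cyclic AMP response, by 2.68. For these 10 genes the highest adjusted p was 4.82e-05. Uty changed by -3.82, Hpgd by -3.79, Igsf6 by -3.77 and Hpse by -3.51. Nsd1 and Ms4a3 changed by -3.04 and -3.03, Ms4a6d by -2.63, F13a1, the A chain of a clotting factor, by -2.58 and the nucleosome-binding gene Hmgn3 by -2.48, with an adjusted p of 0.000351 at most. Of 7 measured genes of the list of the Y chromosome and Xist, limma called 0 upward and 1, Uty, downward, the same adjusted over the list alone. The median change of this list was -0.01 (camera adjusted p = 0.251).

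In all, 1712 of 18193 genes were called, of which 861 rose and 851 fell. At least 2-fold changes were found for 138 that rose and 170 that fell. In 26.2% of all genes the 3 arrays of B117H lay entirely above or below those of B117P, against 10% by chance. The count was 1016 without all A arrays and 587 without all C arrays.

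In B117H camera called the lists of cholesterol synthesis, DNA replication and DNA repair upward and those of neutrophil granules, monocytes and macrophages, and the interferon response downward with the preset correlation, but none of them with an estimated correlation. Members that rose were Mvd and Fdft1, which act before the first sterol is formed, Cyp51, which acts after it, genes of DNA polymerase epsilon, and Xrcc5, which encodes a subunit of the Ku complex for end joining. Members that fell were the lysozyme genes Lyz2 and Lyz1, the transcription factor gene Irf8 and the chemokine gene Cxcl10. Most members of these lists were not called.

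Of 31 measured cholesterol genes, 12 rose and 1 fell in B117H (20 and 2 adjusted over the list alone; camera adjusted p = 5.27e-08, adjusted p = 0.311 with an estimated correlation). Mvd rose by 1.41, Fdft1 by 1.07, the sterol carrier gene Stard4 by 1.07 and Cyp51 by 0.79. Of 42 DNA replication genes, 9 rose and 0 fell by limma (14 and 1 adjusted over the list alone, 19 with an unadjusted p under 0.05; camera adjusted p = 1.17e-06, adjusted p = 0.327 with an estimated correlation). Prim2, the large primase subunit, rose by 0.84, Pole by 0.71 and Pole2 by 0.57. The Prim2 call ended without B117H A (adjusted p = 0.0797), B117H B (0.128), B140H A (0.131), B140H B (0.114) or all A arrays (0.254), the Pole call without all C arrays (0.113), and the Pole2 call without all C arrays (0.0515) or with the mean of its probe sets (0.139). Of 57 DNA repair genes, 5 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 5.89e-05, adjusted p = 0.311 with an estimated correlation). Xrcc5 rose by 1.27 and Ercc5, a nuclease of nucleotide excision repair, by 0.59, a call that ended without B117H C (adjusted p = 0.0514), without all C arrays (0.278) and with the mean of its probe sets (0.0644).

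Of 28 neutrophil granule genes, limma called 0 upward and 8 downward in B117H (1 and 10 adjusted over the list alone, 13 with an unadjusted p under 0.05; camera adjusted p = 3.07e-06, adjusted p = 0.311 with an estimated correlation), with Ms4a3 the largest fall. Of 35 monocyte and macrophage genes, 1 rose and 11 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.000522, adjusted p = 0.327 with an estimated correlation). The macrophage receptor gene Adgre1 was the member that rose, by 1.87, while Lyz2 changed by -1.13, Lyz1 by -1.05 and Irf8 by -1.02. Without probe sets ending in _s_at or _x_at the Lyz1 change was -0.10 (adjusted p = 0.837). Of 40 interferon response genes, 3 rose and 13 fell (3 and 16 adjusted over the list alone; camera adjusted p = 0.000137, adjusted p = 0.311 with an estimated correlation). Ifitm1 changed by -2.15, Rtp4 by -1.71, Cxcl10 by -1.35 and Usp18 by -1.29; the Rtp4 call ended without all C arrays (adjusted p = 0.0633). Of 23 B lymphoid genes, 7 rose and 2 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.149). Vpreb1 led them, Cd24a fell by 2.04, and Dntt and Rag2, which act in the rearrangement of antigen receptor genes, rose by 2.002 and 1.82, the Dntt call ending without all C arrays (adjusted p = 0.0736). Of 28 genes of dendritic cells and antigen presentation, 5 rose and 0 fell, the same adjusted over the list alone, with 9 at an unadjusted limma p under 0.05. Camera gave this list an adjusted p of 0.0882, and 0.0272 without B117H A.

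Camera called 6 of 30 lists with the preset correlation, and 0 with an estimated correlation, by which 4 had an unadjusted p under 0.05. The other 24 lists had adjusted p-values of 0.0882 to 0.990.

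B140H was compared with B140P with the same question. S100a10, which encodes the partner of annexin A2, fell most, followed by Epop, a gene of polycomb complexes, Serpinb8, a protease inhibitor, and Sfmbt2, another polycomb gene. Hp, which encodes the haemoglobin-binding protein haptoglobin, rose most, with Megf9, a membrane protein of neurons and blood cells, and Serinc5, which limits the infectivity of retroviruses, behind it. Hmgn3 and Hpse rose here, and both fell in B117H.

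S100a10 fell from a log2 level of 11.79 ± 0.20 (SD, n = 3) to 6.31 ± 0.31, a change of -5.47 (SE 0.15, adjusted p = 7.29e-10). Epop changed by -3.69, Serpinb8 by -3.54, Sfmbt2 by -3.43 and Sash1, a scaffold protein gene, by -3.20. Fbxl5, a ubiquitin ligase subunit that senses iron, changed by -3.12, ahead of Dck, and Gnpda2, a deaminase of sugar phosphates, by -2.95. Gem, a small GTPase gene, changed by -2.78, and Hacd1, which acts in fatty acid elongation, by -2.76. Hp rose by 3.09, Megf9 by 3.01 and Serinc5 by 2.93. Arap3, a GTPase-activating protein gene, and Zscan26, a zinc finger gene, rose by 2.74 and 2.74, Hmgn3 by 2.67, Hpse by 2.44 and Phka1, a subunit of phosphorylase kinase, by 2.33. The highest adjusted p among these 18 genes was 0.000219. Without probe sets ending in _s_at or _x_at another probe set stood for Arap3 and was not called (adjusted p = 0.169).

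In all, 1194 of 18193 genes were called in B140H, of which 512 rose and 682 fell, and 1827 were called with the replicate letter as a block, among them all 1194. At least 2-fold changes were found for 72 that rose and 127 that fell. With each array centred on its median, 33.4% of 1121 called genes rose, against 42.9% of the 1194. The arrays of B140H and B140P did not overlap in 23.7% of all genes, against 10% by chance. The count was 750 without B140P A, 745 without B140P B, 762 without B140P C, 682 with only the pair's 6 arrays in the fit, 482 without all A arrays and 378 without all C arrays.

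With the preset correlation camera called the list of DNA replication upward in B140H, as in B117H, and in neither line with an estimated correlation. Of myeloid markers, the granule genes Hp and Mmp8, a collagenase, rose while Mpo, which encodes myeloperoxidase, fell. Cholesterol genes were not called as a group, although Elovl6, which elongates fatty acids, fell.

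Of 42 DNA replication genes, 4 rose and 0 fell in B140H by limma (15 and 0 adjusted over the list alone, 18 with an unadjusted p under 0.05; camera adjusted p = 2.16e-05, adjusted p = 0.930 with an estimated correlation). Rfc2, a subunit of the clamp loader, rose by 0.94. Of 28 neutrophil granule genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.414), with Hp first, Mpo at -2.41 and Mmp8 at 1.93. Of 35 monocyte and macrophage genes, 3 rose and 3 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.662), and Mpeg1, a pore-forming protein of macrophages, rose by 2.02 while the cathepsin gene Ctsl fell by 1.42. Of 40 interferon response genes, 4 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.657), the 1 being Ifitm1. Of 31 cholesterol genes, limma called 0 upward and 1 downward, the same adjusted over the list alone, with 3 at an unadjusted p under 0.05. That 1 was Elovl6, at -2.44. Camera put the cholesterol list downward (adjusted p = 0.613), with a median change of 0.00 and a mean of -0.06.

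Of 57 DNA repair genes, 3 rose and 6 fell in B140H (7 and 6 adjusted over the list alone; camera adjusted p = 0.536). Xrcc5 fell by 2.10. Of 23 B lymphoid genes, 3 rose and 4 fell (5 and 5 adjusted over the list alone). Pou2af1, a coactivator gene of B cells, changed by -2.69 and Dntt by -1.91, a call that ended without all C arrays (adjusted p = 0.0979), while the receptor gene Cd22 rose by 1.64. Camera put the B lymphoid list upward (adjusted p = 0.883), with a median of 0.15 and a mean of -0.07. Of 28 genes of dendritic cells and antigen presentation, 1 rose and 0 fell (2 and 0 adjusted over the list alone, 6 with an unadjusted limma p under 0.05; camera adjusted p = 0.613).

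Camera called 1 of 30 lists with the preset correlation in B140H, and 0 with an estimated correlation, by which 0 had an unadjusted p under 0.05. Without B140P C it called 2, the list of the unfolded protein and amino acid response being added (adjusted p = 0.0145). Without B140H A it called 3, with this list (adjusted p = 0.0415) and that of glycolysis and hypoxia (0.00183) added.

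**Figure D2:**
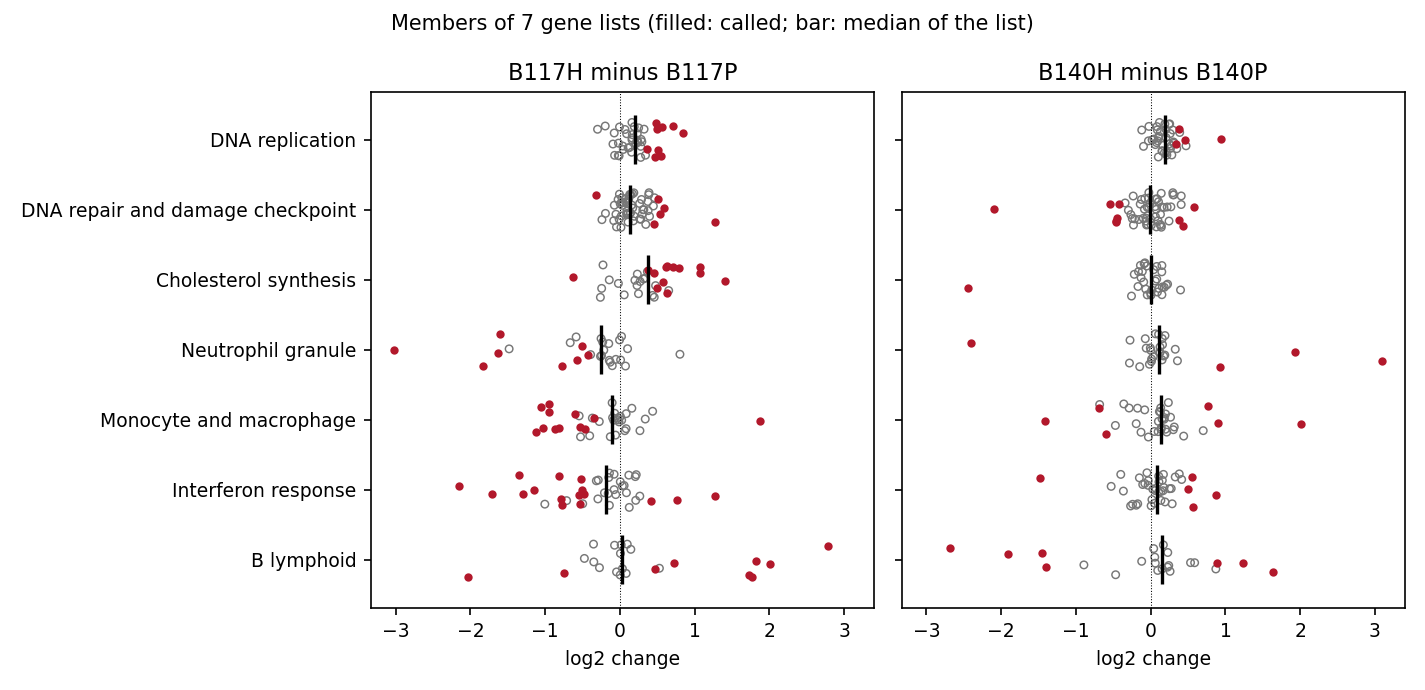
Log2 change of each member of 7 gene lists in B117H minus B117P and in B140H minus B140P, with called genes filled and a bar at the median of each list. The median of the 42 DNA replication genes is 0.20 in both pairs, and that of the 31 cholesterol genes is 0.38 in B117H and 0.00 in B140H.

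Genes that changed alike in both resistant lines were sought next, since both lines had come to tolerate the same drug. Dck led those that fell, followed by Dab2, an adaptor of endocytosis, the interferon-induced gene Ifitm1, Psph, which catalyses the last step of serine synthesis, and Kyat3, an aminotransferase of the kynurenine pathway. Kmo, another enzyme of that pathway, rose in both. Aff3, a nuclear factor gene of lymphoid cells, Slc14a1, a urea transporter gene, and Bcl10, a signalling adaptor of lymphocytes, rose in both as well. Bcl10 rose together with neighbouring genes at the distal end of chromosome 3.

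Aff3 rose by 1.45 in B117H and 1.12 in B140H, and Slc14a1 by 1.41 and 1.08. Cryz, a quinone reductase gene, rose by 1.11 and 1.03, Ankrd13c by 1.04 and 1.01, the centrosome gene Ninl by 2.56 and 0.93, and Myl10 by 0.94 and 0.91. Bcl10 rose by 1.14 and 0.88, Kmo by 0.91 and 0.84, Ctbs, a lysosomal chitobiase gene, by 0.92 and 0.84, and Ssx2ip by 0.84 and 0.90. Bcl10, Cryz, Ankrd13c, Ctbs and Ssx2ip all lie at the distal end of chromosome 3, which held 23 of the 59 genes that rose in both. Dab2 changed by -2.12 and -1.70, Ifitm1 by -2.15 and -1.48, Psph by -2.19 and -1.38 and Kyat3 by -1.12 and -1.72. In B140H the call of Cryz ended without B140P B (adjusted p = 0.0549), and that of Kmo without B140P A (0.0671) or B140H C (0.0507). The B140H call of Ninl ended without B140P A (adjusted p = 0.0644), B140P B (0.0875), B140H A (0.0743) or B140H C (0.0628), and with only the pair's arrays in the fit (0.0712). Without all A arrays Bcl10 was called in neither line, with a change of 0.47 in B117H (adjusted p = 0.191) and 0.40 in B140H (0.380), nor was Cryz (0.0556 and 0.0819), and Aff3 (0.0581), Slc14a1 (0.0525) and Ninl (0.184) were not called in B140H. Without all C arrays Cryz was called in neither line (adjusted p = 0.106 and 0.111), Ssx2ip (0.0589) and Kyat3 (0.104) not in B117H, and Kmo (0.150), Ninl (0.165) and Ifitm1 (0.0629) not in B140H.

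Called in both lines in the same direction were 107 genes, against 56.1 for independent lists: 59 rose (24.2) and 48 fell (31.9). At least 2-fold in both, 4 rose and 5 fell. The 107 became 199 with the replicate letter as a block, 66 with only each pair's own arrays in the fit and 66 without B140P B. More genes moved in opposite directions, 166 against 56.2 for independent lists, of which 101 rose in B117H and fell in B140H and 65 did the reverse. Both pairs share the estimate of each gene's spread, so a gene with a small spread is called more easily in both. Independent lists therefore understate the overlap to be had without a common cause, in either direction. Across all 18193 genes, which are not independent replicates, the changes of both pairs correlated at -0.0821 (Pearson) and -0.115 (Spearman). Pearson's value was -0.0505 without B140H B, -0.0534 without B117P A and -0.0396 with array weights.

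**Figure D3:**
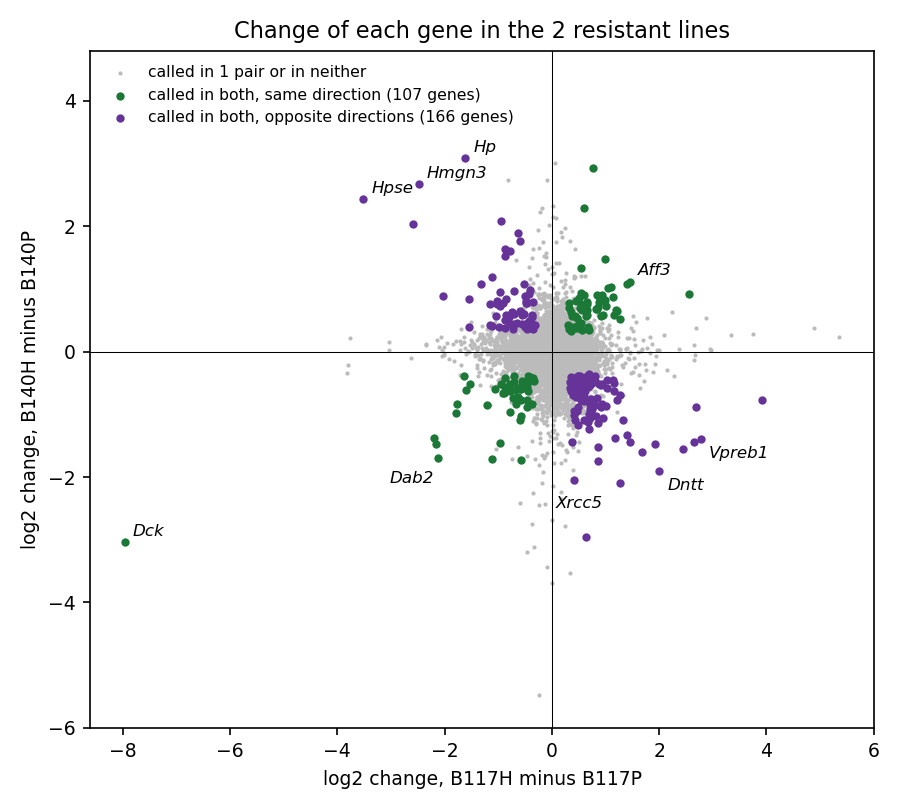
Log2 change of each gene in B117H minus B117P (horizontal) and in B140H minus B140P (vertical), with the 107 genes called in both in the same direction and the 166 called in opposite directions in colour. Dck lies at -7.96 and -3.04.

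The average of both pairs was taken to find changes of the resistant lines together, though it can rest on 1 line alone. With the preset correlation camera called the list of DNA replication upward, which it also called in each pair. It called the cholesterol list upward too, but of the pairs this list was called in B117H alone. Lists of monocytes and macrophages, of the interferon response and of NF-kB and inflammatory cytokines were called downward, although most of their members were not called and the called ones went both ways. None of these lists was called with an estimated correlation. Dck changed by -5.50 (adjusted p = 1.03e-12). Of 18193 genes, 1430 were called, 671 of them higher and 759 lower, and 41 and 53 by at least 2-fold. With each array centred on its median, 39.2% of 1352 called genes rose, against 46.9% of the 1430. The count was 693 without all A arrays and 393 without all C arrays.

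Of the 42 DNA replication genes, 11 rose and 0 fell on average by limma (22 and 0 adjusted over the list alone, 28 with an unadjusted p under 0.05; camera adjusted p = 1.11e-11). Of the 31 cholesterol genes, 7 rose and 2 fell (15 and 2 adjusted over the list alone; 0.000798). Monocyte and macrophage genes gave 4 that rose and 7 that fell of 35 (4 and 9 adjusted over the list alone; 0.0484), interferon response genes 6 and 6 of 40 (6 and 9 adjusted over the list alone; 0.0231) and genes of NF-kB and inflammatory cytokines 1 and 2 of 44 (1 and 3 adjusted over the list alone; 0.0231). With an estimated correlation each of these 5 lists had an adjusted p of 0.635, camera called 0 lists and 1 had an unadjusted p under 0.05. The call of monocytes and macrophages ended with the replicate letter as a block (adjusted p = 0.0554), with arrays centred on their medians (0.0667), with brighter probe sets only (0.0723), with the mean of a gene's probe sets (0.106), without probe sets ending in _s_at or _x_at (0.120), without all C arrays (0.114) and without B117P A (0.0504), B117P B (0.0633), B117P C (0.0543), B117H A (0.0539), B117H B (0.0871), B140P A (0.0881) or B140H C (0.162). That of the interferon response ended with brighter probe sets only (adjusted p = 0.212) and without B117H A (0.0539) or B140H B (0.128), and that of NF-kB and inflammatory cytokines with brighter probe sets only (0.174) and without B117P B (0.0721), B117H A (0.0539) or B140H B (0.0513). Without B117H A, 2 lists were called.

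The difference between the lines asked where the changes of B140H and B117H parted. Hpse, Hmgn3 and F13a1 went down in B117H and up in B140H, and Hp did the same. Xrcc5 and Dntt went up in B117H and down in B140H. With the preset correlation camera called the lists of cholesterol synthesis and DNA repair for a more upward change in B117H, and those of neutrophil granules, monocytes and macrophages, and the interferon response for a more upward change in B140H. It called none of them with an estimated correlation.

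The difference in change, B140H minus B117H, was 5.95 for Hpse (adjusted p = 3.28e-08), -5.23 for S100a10 (3.28e-08), 5.15 for Hmgn3 (8.55e-07) and -5.11 for Glul (8.06e-08). F13a1 changed by -2.58 in B117H and 2.03 in B140H (adjusted p = 0.0032), and Hp by -1.61 and 3.09. For Xrcc5 the difference was -3.36 (adjusted p = 1.32e-06), for Dntt -3.91 (0.000254) and for Irf8, which rose by 0.76 in B140H (adjusted p = 0.0597 without all A arrays), 1.78 (3.47e-05). In all, 1896 of 18193 genes were called for the difference, 894 with the more positive change in B140H and 1002 with the more positive change in B117H. With each array centred on its median, 41.8% of 1777 called genes had the more positive change in B140H, against 47.2% of the 1896. The count was 901 without all A arrays and 574 without all C arrays.

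Camera called 6 lists for the difference. Of 31 cholesterol genes, 1 changed more upward in B140H and 5 in B117H (1 and 15 adjusted over the list alone; adjusted p = 1.80e-06), and of 57 DNA repair genes 1 and 7 (1 and 9 adjusted over the list alone; 0.00189). Of 28 neutrophil granule genes, 7 changed more upward in B140H and 1 in B117H (10 and 2 adjusted over the list alone; 0.000198). Of 40 interferon response genes these numbers were 10 and 1 (17 and 2 adjusted over the list alone; 0.00212), and of 35 monocyte and macrophage genes 9 and 3 (10 and 4 adjusted over the list alone; 0.0144), a call that ended without probe sets ending in _s_at or _x_at (0.0643). With an estimated correlation the adjusted p was 0.366 for the first 4 of these lists and 0.581 for monocytes and macrophages. The ribosomal protein genes, 36 measured, were lower as a group in the difference (adjusted p = 0.0330, adjusted p = 0.890 with an estimated correlation), though 1 was called upward and 0 downward, the same adjusted over the list alone, with 7 at an unadjusted limma p under 0.05. That call ended with quantile normalization applied again (adjusted p = 0.287), with brighter probe sets only (0.132), without probe sets ending in _s_at or _x_at (0.132), and without B117P A (0.0669), B117H C (0.0792), B140P C (0.0671), B140H A (0.0592), all A (0.0571) or all C arrays (0.163). With an estimated correlation camera called 0 lists, and 2 had an unadjusted p under 0.05.

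Neighbouring genes moved together on several chromosomes. In B117H camera called chromosome 12 upward and chromosomes 13 and 16 downward with the preset correlation. In B140H it called chromosomes 9, 12 and 14 downward and chromosome 5 upward, so chromosome 12 was called in opposite directions in the resistant lines. No chromosome was called with an estimated correlation. Chromosome and gene order came from the reference gene table of assembly GRCm38.p6.

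On chromosome 12, 143 of 622 genes rose and 4 fell in B117H (camera adjusted p = 1.52e-11), and 3 rose and 41 fell in B140H (adjusted p = 4.64e-05, adjusted p = 0.750 with an estimated correlation). In B117H 9 of 593 genes of chromosome 16 rose and 125 fell (adjusted p = 3.86e-11), and 20 of 702 genes of chromosome 13 rose and 152 fell (2.92e-07). Each of the 3 chromosomes of B117H had an adjusted p of 0.178 with an estimated correlation. In B140H 9 of 1002 genes of chromosome 9 rose and 134 fell (adjusted p = 3.33e-06, adjusted p = 0.518 with an estimated correlation), and 3 of 641 genes of chromosome 14 rose and 105 fell (adjusted p = 2.96e-07, adjusted p = 0.518 with an estimated correlation). On chromosome 5, 88 of 1122 genes rose and 14 fell in B140H (adjusted p = 0.00426, adjusted p = 0.975 with an estimated correlation). With an estimated correlation camera called 0 of 21 chromosomes in either pair, and 3 in B117H and 2 in B140H had an unadjusted p under 0.05. Chromosome 1 was called upward in B117H without B117P B (adjusted p = 0.0227) or B117P C (0.0389), with quantile normalization applied again (0.0447) and with brighter probe sets only (0.00265). Brighter probe sets only also called chromosome 5 downward in B117H (adjusted p = 0.0383) and chromosome 3 downward in B140H (0.0136).

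Windows of neighbouring genes, a test chosen after these shifts had been seen, placed them on parts of chromosomes. Each window was 10 Mb long by the reference positions and held at least 10 of the genes brighter than the median probe set, which alone entered. Camera called 46 of 243 windows in B117H, 19 up and 27 down, and 39 in B140H, 10 up and 29 down. With an estimated correlation it called 20 and 23, and 15 and 16 when the replicate letter was also a block. In B117H, from Gdi2 to Tut7 on chromosome 13, 139 of 217 genes fell and 2 rose, with a median of -0.62. From Selenop to Dcstamp on chromosome 15, 38 of 73 fell and 1 rose (median -0.69), and the 323 genes from Nubp1 onward on chromosome 16 had a median of -0.31. From Rab10os to Sp4 on chromosome 12, 141 of 406 genes rose and 4 fell (median 0.30). The part of chromosome 5 that holds Dck, from Cenpc1 to Zfp932, had 37 of 91 genes down and 1 up in B117H (median -0.31). In B140H, 122 of 420 genes from Alkbh8 to Sox14 on chromosome 9 fell and 5 rose (median -0.30), as did 97 of 260 from Tspan14 to Tmtc4 on chromosome 14, where 2 rose (median -0.34). At the distal end of chromosome 3, 25 of 41 genes from Unc5c to Wls rose and 4 fell in B117H (median 0.63), and 43 of 72 from Col25a1 to Wls rose and 1 fell in B140H (median 0.57). Of the 2 windows of this part in B117H, 1 was not called with an estimated correlation (adjusted p = 0.242). The called windows held 15.4% of genes and 40.1% of the calls in B117H, and 17.0% and 44.1% in B140H. They were picked by these same changes, so a larger share of the calls inside them follows from the choice.

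**Figure D4:**
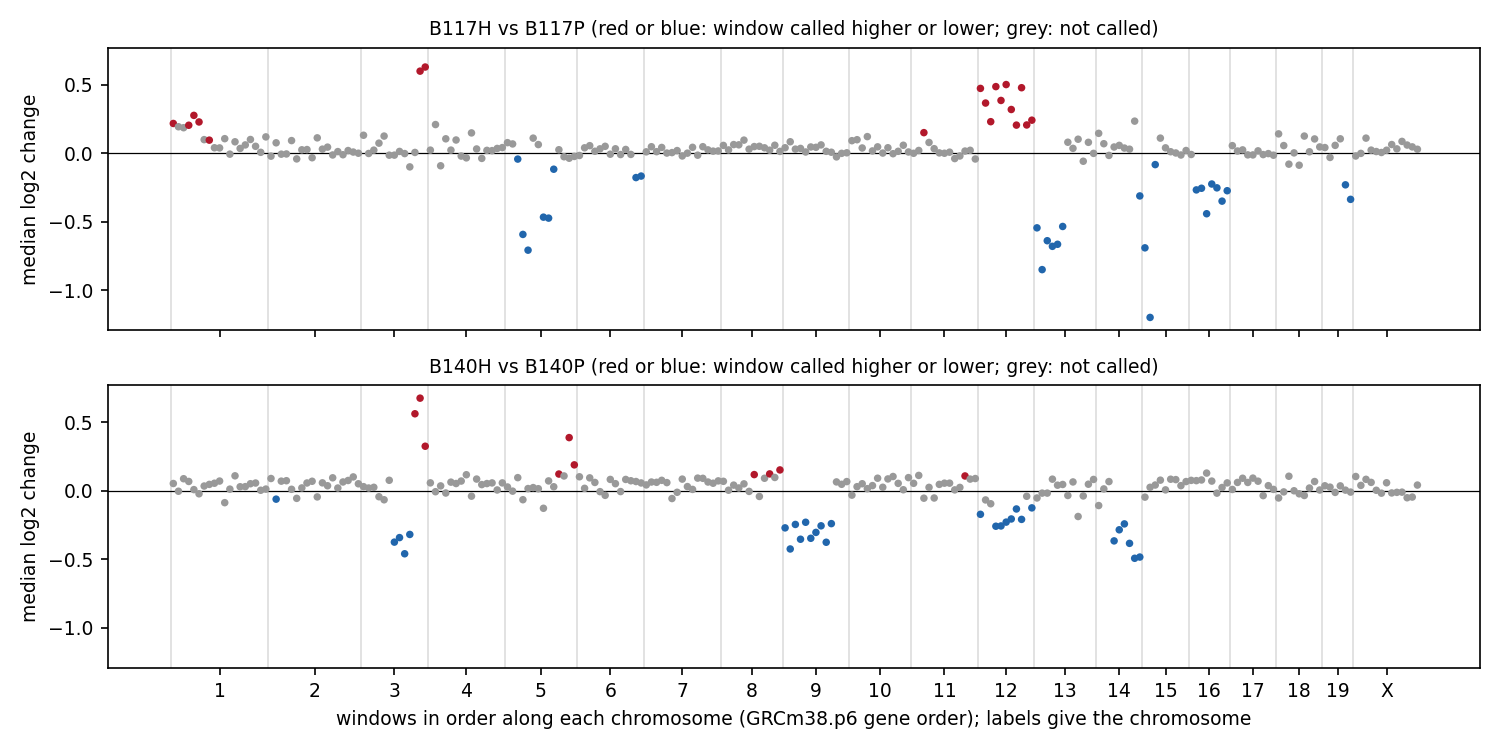
Median log2 change of brighter genes in 243 windows in order along the chromosomes, for B117H minus B117P (top) and B140H minus B140P (bottom), with called windows coloured. Chromosome 12 lies above 0 in B117H and below 0 in B140H.

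The parental lines were compared to show how far the lineages differed before resistance. Of the genes named for the resistant lines, Mpo, the lysozyme genes Lyz1 and Lyz2, and Ms4a3 were far lower in B140P than in B117P. Glul, which rose in B117H, was already high in B140P.

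Mpo stood at a log2 level of 14.62 in B117P and 9.54 in B140P, a difference of -5.08 (adjusted p = 3.19e-08). The difference was -6.42 for Lyz1, -6.17 for Ms4a3, -4.69 for Lyz2 and 5.59 for Glul (adjusted p = 7.46e-11). For Lyz1 it rests on a probe set with a name ending in _s_at or _x_at, without which its change in B117H was not called. Between the parental lines 4333 of 18193 genes were called, 2178 higher and 2155 lower in B140P, and 487 and 727 by at least 2-fold. The arrays did not overlap in 38.6% of all genes, against 10% by chance. Without all C arrays the count was 2698.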

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

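The tests of the genes around Dck and of its other probe set were chosen only after the results they measure were seen. So were those of shuffled gene order, of the array letters, of adjoining windows and of genes at least 8-fold higher in the B140 lines. The tests of opposite changes outside segments, of genes near the floor and of other splits were not. The test outside segments still rests on windows chosen after the data had been seen.

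Dck, whose product activates Ara-C, fell in both resistant lines. Loss of a region that takes in the 10 nearest brighter genes on chromosome 5 is argued against as the whole cause. These genes, 44.1 to 1726 kb away, had a median change of -0.640 in B117H (SD 0.448, 6 called downward). In B140H it was -0.0169 (SD 0.160, limma called 0 downward). Both are far from the -7.96 and -3.04 of Dck. On one side of Dck the nearest of these genes, Cox18, lies 1449711 bases away, so a loss that ends before it would not have been seen. A fault of its probe set is argued against by its next brightest probe set, which changed by -6.43 in B117H. A change in Dck itself, such as a small deletion, a splice or stability defect or silencing, may be the cause and was not tested, and in B117H it could come on top of a smaller change of the region. The third probe set, which changed by -0.12 in B117H, may read a part of the gene or another transcript, and the binding places of the probes were not used here.

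Neighbouring genes moved together along chromosomes, such as chromosome 12 in opposite directions in the resistant lines and chromosomes 13 and 16 in B117H. Chance placement is argued against, since 0 of 100 shuffles of gene order gave as many windows with a median beyond 0.3 log2 units as the 42 seen, and the most that a shuffle gave was 1. A level shared by all arrays of a letter cancels between arrays of that letter, so only a shift confined to some letters could be tested. Such a shift is argued against for the larger windows. Those beyond 0.3 in the pairs of both other letters, 105 picks in all, had a median change of 0.477 in the same direction in the letter left out. The lowest was 0.166. A window could be picked more than once, and neighbouring windows are not independent. Of windows with little change in the other letters, 69.9% also kept their sign. Smaller shifts, such as that of chromosome 12 in B140H, were not covered. Of called windows 81.2% lay beside another called window of the same direction, which restates the pattern and would follow from gain or loss of chromosome segments and from silencing or regulation of whole regions alike. These cannot be told apart, as no DNA measurement was used here.

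More genes moved in opposite directions in the B117 and B140 pairs than independent lists give, Hpse, Hmgn3, Hp, F13a1, Xrcc5 and Dntt among them. Opposite changes of chromosome segments are argued against as the whole cause: outside all called windows 75 genes were opposite against 18.6 for independent lists, a ratio of 4.03, though genes that moved alike were also in excess there (47 against 19.3, a ratio of 2.44). B117 cells in the B140H culture are argued against by 15 genes near the floor in B140P, which reached a median of 0.118% of their B117 level (upper quartile 0.257%). For B140 cells in the B117H culture, 4 genes near the floor in B117P reached a median of 2.06% of their B140 level, too few to decide alone, while 41 genes at least 8-fold higher in both B140 lines reached 0.088% (quartiles -0.31% and 2.27%), which argues against it. The pairs share the estimate of each gene's spread, which can raise the overlap in either direction above that of independent lists, also outside the called windows. How much it did so was not tested. A different response of each lineage, or separate selection of each line, may be the cause, and neither was tested.

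The change differed between the lines, by limma's test of the difference, for 1896 genes and by camera with the preset correlation for 6 lists, but for 0 lists with an estimated correlation, by which 2 had an unadjusted p under 0.05. All gene values that follow are the B140 change minus the B117 change. Dck, the activating kinase, had 4.92, since its fall was smaller in B140H, and this size is not exact. Among genes that rose in B117H, Glul differed by -5.11, Depdc1a by -4.52, Sgpp1 by -4.69, Nrg4 by -3.07, Itgax by -2.92, Slc36a4 by -2.91, Acss2 by -2.33, Vpreb1 by -4.18, Lpcat2 by -2.31 and Crem by -3.57. Among genes that fell there, Uty differed by 3.48, Hpgd by 3.59, Igsf6 by 3.996, Hpse by 5.95, Nsd1 by 3.07, Ms4a3 by 3.18, Ms4a6d by 2.53, F13a1 by 4.61 and Hmgn3 by 5.15.

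Among genes that rose in B140H, the difference was 4.70 for Hp, 2.96 for Megf9, 2.16 for Serinc5, 2.84 for Arap3, 3.54 for Zscan26 and 2.30 for Phka1. Among those that fell, it was -5.23 for S100a10, -3.69 for Epop, -3.87 for Serpinb8, -3.35 for Sfmbt2, -2.74 for Sash1, -2.79 for Fbxl5, -3.58 for Gnpda2, -3.02 for Gem and -2.39 for Hacd1. Ninl, which rose in both lines, differed by -1.63, and Psph, which fell in both, by 0.81.

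In the replication and repair lists the difference was -0.87 for Prim2, -0.69 for Pole2, 0.70 for Rfc2 and -3.36 for Xrcc5. Of sterol and fatty acid genes, Mvd differed by -1.197, Fdft1 by -1.33, Stard4 by -1.06 and Elovl6 by -2.19. Of interferon genes, Rtp4 differed by 1.87, Cxcl10 by 0.82 and Usp18 by 1.71. Of myeloid genes, Adgre1 differed by -1.74, Mpo by -1.82 and Ctsl by -1.05, but Lyz2 by 1.34, Lyz1 by 1.15, Irf8 by 1.78, Mmp8 by 2.19 and Mpeg1 by 2.07. The Lyz1 value rests on a probe set with a name ending in _s_at or _x_at. Of genes of early B cells, Dntt stood at -3.91, Rag2 at -1.60, Pou2af1 at -2.69, Cd24a at 2.92 and Cd22 at 1.99.

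Of the transporter genes, Abcc2 differed by 1.74 and Abcb4 by 0.70. Of the genes of cell death, Ripk3 differed by -1.61, Casp6 by -0.74, Mcl1 by -0.91 and Bcl2 by 1.02. The stress genes Mt2, Hmox1, Gstm1 and Dnajb4 differed by -1.16, 1.34, 1.49 and -1.82. Psat1, of serine synthesis, differed by -0.72, Gart, of purine synthesis, by 0.61, Mn1 by 1.47 and Cebpb by 1.55.

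Other splits of the same arrays were counted for each result, the real split included. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Every other split mixes arrays of both lines, which puts their difference into the spread and lowers its gene count. It also keeps part of the real change, so its lists and chromosomes do not measure chance alone. In B117H 1 split gave as many genes as the real 1712, and the highest other count was 1 (3633 and 1358 genes at an unadjusted p under 0.05). As many lists as the real 6 came from 4 splits (highest other 8), and as many chromosomes as the real 3 from 5 (highest other 3). In B140H 1 split gave as many genes as the real 1194, and limma called 0 in any other (3383 and at most 1699 genes at an unadjusted p under 0.05). As many lists as the real 1 came from all 10 splits (highest other 6), and as many chromosomes as the real 4 from 1 (highest other 3). The letters pair the B140 arrays, and A and C also match in the B117 pair. Of the 10 splits, 4 part all 3 letters, and the other splits of this kind gave up to 6 lists and 3 chromosomes. Between the parental lines 1 split gave as many genes as the real 4333, and limma called 0 in any other (5826 and at most 942 at an unadjusted p under 0.05).

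For results that use all 4 lines, 100 splits within the pairs were drawn of 200. As many genes as the 1430 of the average came from 2, the other (1896) being the real split with one pair turned around, which turns the average into the difference. As many genes as the 1896 of the difference came from 1 (highest other 1430, again the turned pair). The remaining 98 splits gave at most 564 and 646 genes, so a random grouping of the arrays is argued against for these counts. Chance differences between single lines cannot be excluded, since each group is 1 line. The splits also ignored the letters, and mixed splits put differences between lines into the spread, which lowers their counts. As many shared genes as 107 came from 2 (highest other 166, the turned pair), but limma gave 0 shared genes in each of the remaining 98, since few genes are called in a pair that is split otherwise, so this says nothing on whether the lines share more genes than chance gives. As many lists as the 5 of the average came from 31 splits and as many as the 6 of the difference from 29, with up to 9 lists in others, so chance cannot be excluded for these numbers of lists.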

How the results depend on the processing

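The tests without a pseudocount, without probe sets ending in _s_at or _x_at, without all A or all C arrays, and of lists without genes of moved segments were chosen only after the results were seen. No result reversed. Of 202 changes of named genes, Dck among them, 127 were called; 92 of these kept their call under every alternative but the stricter p and the fold test, and 115 did so without any single array. Of 5216 checks of these genes 5030 gave the same call, 165 were weaker and 21 stronger. The fold test ended 57 of the named calls, the stricter p 11, the loss of all A arrays 14 and of all C arrays 25.

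An adjusted p under 0.01 called 1007 genes in B117H, 629 in B140H, 755 in the average, 1006 in the difference and 49 in both lines alike, and 2 lists in the average, fewer by construction. A test against a fold of 1.5 called 174, 96, 56 and 248 genes, 1123 between the parental lines and 4 in both lines alike, also by construction. Without all A arrays 1016, 482, 693 and 901 genes were called and 48 in both alike; without all C arrays 587, 378, 393, 574, 2698 between the parental lines and 22. Fits on a pair's own arrays called 682 genes in B140H and 66 alike. The cause was not tested; for the average and the difference this alternative is the same fit.

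The replicate letter as a block called 1827 genes in B140H, where the letters pair the arrays, and 199 alike, and ended the monocyte and macrophage call of the average (adjusted p = 0.0554). Between the arrays of B117P and B117H, deviations correlated at 0.555 for A, 0.0278 for B and 0.392 for C, so only A and C matched. The block called 2381 genes there. It added the call of Ripk3 in B117H (adjusted p = 0.0494) and changed no other call of a named gene, a list or a chromosome.

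With an estimated correlation camera called 0 lists in each of the 4 comparisons (4, 0, 1 and 2 at an unadjusted p under 0.05) and 0 chromosomes in B117H and in B140H (3 and 2). The p-value did not rise for every list with it. For apoptosis regulators camera's unadjusted p went from 0.231 to 0.197 in B117H and from 0.141 to 0.122 in B140H. Why the called lists lost their calls was not tested. Without genes of moved segments camera called 7 lists in B117H, 1 in B140H, 6 in the average and 5 in the difference, against 6, 1, 5 and 6 with them. Brighter probe sets only gave 3 lists in the average and 5 chromosomes in B117H; the cause was not tested. The correlation of the pairs was -0.115 by Spearman and -0.0396 with array weights; the cause was not tested.

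Without 1 array at a time the counts ran from 1172 to 1915 genes in B117H, 745 to 1258 in B140H, 1030 to 1453 in the average, 1445 to 1881 in the difference, 3586 to 4610 between the parental lines and 66 to 108 alike. The lowest B140H counts came without B140P A (750), B140P B (745) and B140P C (762), and the 66 without B140P B. The correlation ran from -0.101 to -0.0505, the latter without B140H B and -0.0534 without B117P A. Lists ran from 6 to 7 in B117H, 1 to 3 in B140H (2 without B140P C, 3 without B140H A), 2 to 6 in the average (2 without B117H A) and 5 to 8 in the difference, and chromosomes from 3 to 4 in B117H and 4 to 4 in B140H. The low values of Dck in B117H and of other dim genes lie where RMA signals come close to background, so their folds are limited by it.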

Other observations

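The comparison of C with A arrays and the count on distal chromosome 3 are tests chosen only after the results were seen.

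Of drug transporters of the ABC family, Abcc2 and Abcc4, which export conjugated drugs and nucleotides, changed by -1.71 and -0.66 in B117H, the Abcc4 call ending without all C arrays (adjusted p = 0.0572). In B140H Abcb4, a phospholipid transporter, rose by 1.04 and Abcc4 fell by 0.84. Of 13 such genes limma called 0 upward and 3 downward in B117H (2 and 3 adjusted over the list alone, 6 with an unadjusted p under 0.05; camera adjusted p = 0.149), and 1 upward and 1 downward in B140H (1 and 1 adjusted over the list alone; 0.613).

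Among genes of cell death, Ripk3, the kinase of necroptosis, fell by 1.31 in B140H, the survival gene Bcl2 rose by 1.04, and Casp6 and Mcl1 changed by -0.86 and -0.86. Of 39 apoptosis regulators, 2 rose and 1 fell in B117H (2 and 1 adjusted over the list alone; camera adjusted p = 0.441), and 1 rose and 4 fell in B140H (2 and 4 adjusted over the list alone; 0.414).

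In B140H Phgdh, Psat1 and Psph, which encode enzymes of serine synthesis, changed by -0.61, -1.002 and -1.38; the Phgdh call ended without all A arrays (adjusted p = 0.0627) and without all C arrays (0.0532). In B117H Psph fell, while Phgdh changed by -0.22 (adjusted p = 0.365) and Psat1 by -0.28 (adjusted p = 0.264). Of 45 genes of the unfolded protein and amino acid response, 4 rose and 1 fell in B117H (8 and 3 adjusted over the list alone; camera adjusted p = 0.441). In B140H limma called 0 upward and these 3 downward, the same adjusted over the list alone, with 7 at an unadjusted p under 0.05 (camera adjusted p = 0.0992, but 0.0145 without B140P C and 0.0415 without B140H A, and 0.930 with an estimated correlation).

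The metallothionein gene Mt2 changed by -1.73 in B140H and by -0.57 in B117H, where the call ended without all C arrays (adjusted p = 0.134). Hmox1, which degrades haem, rose by 1.35 in B140H, and the glutathione transferase gene Gstm1 fell by 1.204 in B117H. Of 39 genes of glutathione and oxidative stress, 4 rose and 4 fell in B117H (4 and 5 adjusted over the list alone; camera adjusted p = 0.888), and 2 rose and 3 fell in B140H (2 and 3 adjusted over the list alone; 0.776). The chaperone genes Dnajb4 and Hspa1b rose, by 2.08 in B117H and by 1.21 in B140H. Of 22 heat shock genes, limma called 1 upward and 0 downward in B117H (1 and 1 adjusted over the list alone, 4 with an unadjusted p under 0.05; camera adjusted p = 0.857), and 2 and 1 in B140H (3 and 1 adjusted over the list alone; 0.785).

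In the synthesis of deoxynucleotides, which compete with Ara-C, Tyms rose by 0.67 and Gart fell by 0.60 in B117H; the Tyms call ended with the mean of its probe sets (adjusted p = 0.221) and without all C arrays (0.141), and the Gart call without all A (0.0507) or all C arrays (0.100). Of 36 such genes, 3 rose and 3 fell in B117H (3 and 4 adjusted over the list alone; camera adjusted p = 0.826), and limma called 0 in B140H, also 0 adjusted over the list alone, with 5 at an unadjusted p under 0.05 (0.785). At genes where retroviruses often insert in BXH-2 leukaemias, Mn1 and Cebpb changed in B117H by -1.69 and -1.54. Of 37 of these genes, 1 rose and 5 fell in B117H (3 and 7 adjusted over the list alone; camera adjusted p = 0.570), and 3 rose and 2 fell in B140H (3 and 3 adjusted over the list alone; 0.613).

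Of the 59 genes that rose in both lines, 23 lay at the distal end of chromosome 3, Bcl10, Cryz, Ankrd13c, Ctbs and Ssx2ip among them. This end was taken as beyond 130 Mb, where 141 genes were measured. Elsewhere 36 genes rose in both, against 21.5 for independent lists, a number that takes no account of the shared estimate of spread.

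With the line as a term, 1153 genes differed between C and A arrays, 681 higher and 472 lower in C. Chosen after their values were seen, Igfbp5 was higher in C by 1.63, and Ammecr1 and Zfp800 differed by -1.49 and -1.38. Of 30 lists camera called that of B lymphoid genes, of which 5 of 23 were higher in C (adjusted p = 0.00827). Deviations of arrays from their line's mean correlated between lines at 0.455 or more for A and 0.355 or more for C in each pair of lines, and at -0.0432 to 0.367 for B.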
